A study of Mus musculus with 4 samples.

How the data were processed

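Single-cell RNA was measured in the left liver lobes of female C57BL/6 mice at postnatal day 15, from 2 Jag1+/+ and 2 Jag1+/- animals. The livers were dissociated with a protease that works in the cold, and droplet libraries were made with the 3′ chemistry of 10x Genomics. Each library is 1 animal according to the labels, and the replicate numbers follow the sample titles. The deposited matrices hold raw UMI counts per gene and barcode, and the barcodes had already been called as cells. Cell Ranger 3.0.2 and the mouse genome build mm10 are named in the submitters' processing notes. The settings of the cell calling, the filters on cells and the sequencing depth in reads are not given in the sources used here. The deposited annotation gives each barcode an ICGS2 cluster number from 1 to 40 and no cell type name, and barcodes without a cluster were left out.

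The libraries held 12481 and 13842 barcodes in Jag1+/+ replicates 1 and 2, and 11078 and 12039 in Jag1+/- replicates 1 and 2. Of these, 10738, 12689, 10032 and 10913 were annotated, 44372 cells in total. Gene positions were taken from GENCODE vM21 on mm10. The median UMI count per annotated cell was 2703.5 and 7061 in Jag1+/+ and 7064 and 3597 in Jag1+/-, so that each genotype held 1 deeper and 1 shallower library. Ratios within the deeper pair (Jag1+/+ replicate 2 and Jag1+/- replicate 1) and within the shallower pair (Jag1+/+ replicate 1 and Jag1+/- replicate 2) were computed on CPM plus 1 and are printed beside pooled values. The deposited annotation names the libraries of the deeper pair WTB and JB and those of the shallower pair WT and JAG. What the shared B stands for is not given, and no batch is labelled.

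Clusters were named from 16 marker lists written before the data were examined. A marker counted when its CPM in a cluster was at least 2 times the mean of the other clusters, each with 20 added, and at least 10% of the cells held it. A cluster took the name of the list with most genes among the cluster's 10 leading genes, and between equal lists the one with the larger share of its markers counted. At least 3 markers were required. A cluster with no list gene among those 10 also needed at least 50% of the list and enough UMIs per cell relative to its library. This rule for clusters was changed after the first names had been seen, and 37 of 40 clusters received 1 of 15 names. Alb, Apoa1 and Ttr were among the genes that defined hepatocyte-like clusters, Krt19, Epcam and Spp1 cholangiocyte-like clusters, and Stab2, Clec4g and Lyve1 sinusoidal endothelial-like clusters. Dcn, Lrat and Reln defined stellate-like clusters, Clec4f, Vsig4 and Timd4 Kupffer-like clusters, and Ly6c2, Ccr2 and Lyz2 monocyte- and macrophage-like clusters. S100a8, S100a9 and Retnlg defined neutrophil-like clusters, Xcr1, Clec9a and Siglech dendritic-like clusters, and Cd3g, Trbc2 and Nkg7 T- and NK-like clusters. Cd79a, Cd79b and Ighm defined B-like clusters, and Hba-a1, Hbb-bs and Alas2 erythroid-like clusters. The "-like" is dropped from here on. Clusters 8, 18 and 29 stayed unnamed and held 48.1% and 12.1% of the annotated cells of the Jag1+/+ libraries and 13.8% and 36.1% of those of the Jag1+/- libraries.

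UMI counts were summed per library and cell type and compared between genotypes with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (TMM normalization, its default filter on low counts, robust fit). P-values were two-sided and adjusted by Benjamini and Hochberg within each cell type, with a threshold of 0.05. A cell type was tested when every library held at least 20 of its cells, which 10 types met. Cholangiocytes, mesothelial cells, portal and arterial endothelium, central vein endothelium, and basophils and mast cells did not. Cell shares were tested with edgeR on cell counts with the annotated cells of each library as offset. The fold changes are Jag1+/- over Jag1+/+ with the standard error (SE) of the fit, and CPM values are means ± SD over the 2 animals of a genotype. Means of CPM use TMM-scaled totals where a type was tested.

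Before the data were examined, 22 pathway lists and the marker lists were fixed and tested with limma camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01. A list needed at least 5 tested members, and p-values were adjusted over all lists and cell types, separately for pathway and marker lists. Camera with a correlation estimated from the data and the rotation test fry were run beside it. The differences between hepatocytes and each of sinusoidal endothelium, Kupffer cells and B cells were tested as interaction terms in edgeR. An exact permutation test of 2 animals against 2 cannot give a two-sided p below 0.333, so no such test was used.

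The rule for named genes was also fixed before the data were examined. Jag1, Sox4, Sox9, Notch2, Hes1, Hey1, Spp1, Krt19, Krt7 and Epcam were always given. In hepatocytes, cholangiocytes and the pair of other types with most calls, the 5 largest rises and 5 largest falls were named among called genes with a mean CPM of at least 20 in 1 genotype and no overlap between genotypes. Other types gave the 2 largest rises and 2 largest falls, fixed lists up to 4 called members per cell type, and types without a call the 3 genes with the smallest p. A few genes that the rule or the lists would name are not reported here. A gene outside the rule is said to have been chosen after its values were seen. A genotype without a UMI was set to a floor of 3 UMIs over the genotype, and ratios with 1 to 3 UMIs in a genotype are given with an exact 95% binomial interval that covers counting error only.

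The tests were tried on simulated data with 200 genes changed 2-, 4- or 8-fold. The other settings, also chosen beforehand, were DESeq2 1.42.0 size factors or its Wald test, no filter on low counts, the replicate numbers as a block, and stricter cells with at least 500 genes and at most 20% mitochondrially encoded UMIs. Removal of doublets, counts thinned to the shallowest library, other denominators for shares, unmerged clusters, and leaving out each library in turn were among them. With a library left out its genotype has 1 animal, whose variation is assumed to equal that within the other genotype. Scrublet in scanpy 1.11.5 set a threshold that called at most 7 cells per library, so the 6% of cells with the highest scores were removed instead, a choice made after seeing those calls. Added after the data were seen were the libraries paired by depth as a block, hepatocytes with cluster 8, without cluster 4 or from clusters 1, 2 or 3 alone, a test of cholangiocytes below the minimum, hepatocyte lists under left-out libraries, and shares without hepatocytes and unnamed clusters. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the remaining steps.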

Results

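The livers of 2 Jag1+/+ and 2 Jag1+/- mice at postnatal day 15 gave 1 single-cell library each. Jag1+/+ replicates 1 and 2 held 59438090 and 118564889 UMIs, and Jag1+/- replicates 1 and 2 held 100247354 and 72752367. The annotated cells numbered 10738 and 12689 in Jag1+/+ and 10032 and 10913 in Jag1+/-. Hepatocytes gave 2045, 4877, 2554 and 3852 of them in the same order, and cholangiocytes, which line the bile ducts, gave 10, 55, 42 and 110. The median share of mitochondrially encoded UMIs was 22.6% in Jag1+/+ replicate 1 and 10.7%, 8.57% and 8.67% in the other libraries. Stricter cells, with at least 500 genes and at most 20% mitochondrially encoded UMIs, were 41.0% of the annotated cells in Jag1+/+ replicate 1 and 71.2%, 77.8% and 85.5% in the others.

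The labels state that the Jag1+/- mice lack 1 germline copy of Jag1 (ENSMUSG00000027276, chromosome 2, 137081456 to 137116644), the gene of a Notch ligand. Over all named cells Jag1 measured 3.79 and 3.82 CPM in the Jag1+/+ libraries and 3.81 and 3.13 CPM in the Jag1+/- libraries. In stellate cells, where Jag1 stood highest among the tested types, it measured 68.2 and 52.0 CPM against 43.7 and 24.2 CPM, a log2 fold change of -0.79 (SE 0.38). Hepatocyte Jag1 had a log2 fold change of -0.19 (SE 0.28), sinusoidal endothelial Jag1 0.08 (SE 0.36), T and NK cell Jag1 0.36 (SE 0.70) and Kupffer cell Jag1 -0.28 (SE 0.76). Jag1 was called in 0 of these 5 types by edgeR and by DESeq2, and its smallest unadjusted p was 0.0679. The labels do not say which part of Jag1 was deleted, so 3′ tags from the altered copy would leave these levels uninformative about genotype. Xist, the RNA of the inactive X chromosome, measured 787 to 862 CPM in the 4 libraries and 4 Y-linked genes gave 0 to 7 UMIs each per library, the labels giving female sex.

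The first comparison asked whether the distribution of cell types differed between genotypes. Cholangiocytes were 0.0931% and 0.433% of annotated cells in Jag1+/+ and 0.419% and 1.01% in Jag1+/-, a log2 fold change of 1.43 (SE 0.84). The exact 95% binomial intervals were 0.0447% to 0.171% in Jag1+/+ replicate 1 and 0.829% to 1.21% in Jag1+/- replicate 2. Within the deeper pair of libraries the cholangiocyte log2 ratio was -0.05, and within the shallower pair it was 3.44. Monocytes and macrophages took 0.757% ± 0.0436 in Jag1+/+ and 1.68% ± 1.02 in Jag1+/- (SD, 2 animals each), with log2 ratios of 1.61 in the deeper and 0.39 in the shallower pair. Neutrophils took 1.83% ± 0.606 and 3.85% ± 3.34, with 1.46 and 0.10 in the same pairs. Hepatocytes took 28.7% ± 13.7 and 30.4% ± 6.96, and their ratios of -0.59 and 0.89 pointed in opposite directions. Sinusoidal endothelial cells took 9.41% ± 0.787 and 6.84% ± 2.43, with -0.22 and -0.79. B cells took 12.4% ± 8.71 and 14.2% ± 11.4, Kupffer cells 8.95% ± 2.95 and 8.87% ± 5.72, and T and NK cells 3.10% ± 1.75 and 3.72% ± 0.643. Stellate cells took 1.11% ± 0.105 and 0.837% ± 0.436, and dendritic cells 1.72% ± 0.0632 and 2.20% ± 0.293. No share of a class passed the test: edgeR called 0 of 16 classes, with 0 at an unadjusted p under 0.05. The smallest unadjusted p was 0.0995 for cholangiocytes, and the edgeR adjusted p was 0.988 for each class. The SE on the log2 scale was nearly the same in every class, from 0.80 in hepatocytes to 0.90 in basophils and mast cells. Dendritic cells had 0.81 and B cells 0.80, so these p-values do not measure the SD of a single class. With the clusters unmerged, a setting chosen beforehand, the share test called clusters 4 and 35. Cluster 4, of hepatocytes, held 9 and 47 cells in Jag1+/+ and 369 and 884 in Jag1+/-. Cluster 35, of monocytes and macrophages, held 3 and 5 cells against 73 and 25. Cells of unnamed clusters took 30.1% ± 25.5 and 24.96% ± 15.8, and 48.1% of Jag1+/+ replicate 1 alone.

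**Figure D1:**
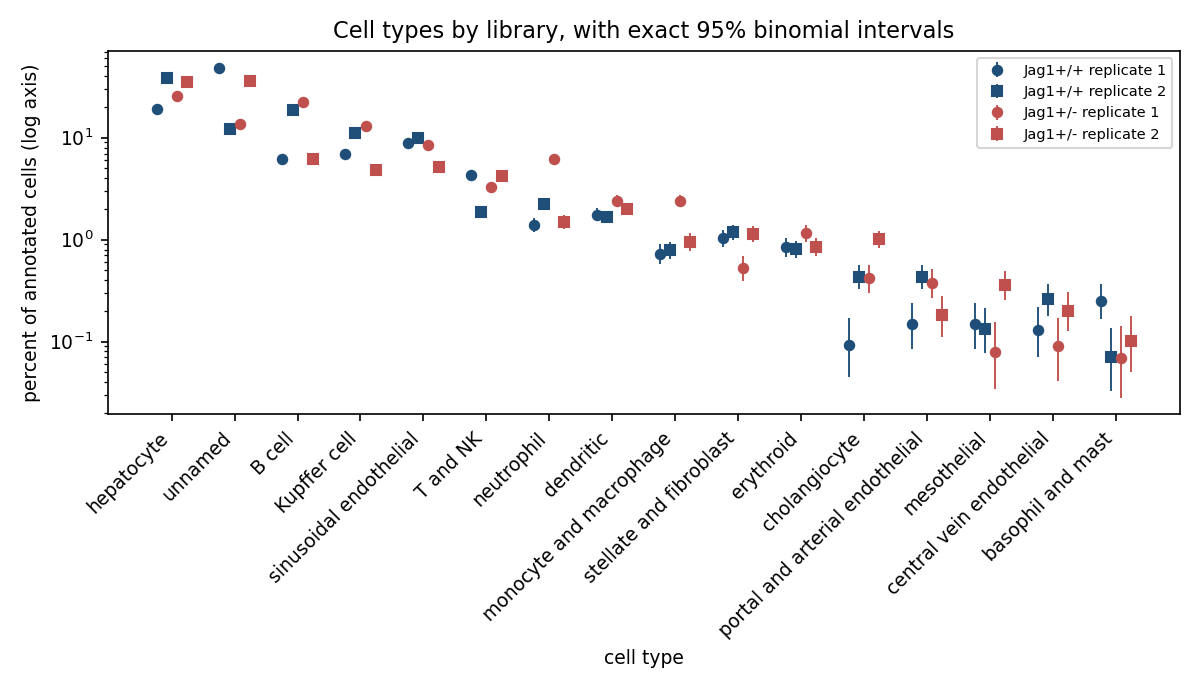
Percent of annotated cells per cell type (log axis) in each library, with exact 95% binomial intervals; blue marks Jag1+/+ and red Jag1+/-. Cholangiocytes ranged from 0.0931% in Jag1+/+ replicate 1 to 1.01% in Jag1+/- replicate 2, while the deeper libraries held 0.433% and 0.419%.

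The second comparison asked which genes and pathways differed in hepatocytes. Of 13689 genes tested, 24 rose in Jag1+/- hepatocytes and 0 fell by edgeR. This fit, like those of the other cell types, did not use the depth pairs as a block. With that block, added after the data were seen, more genes were called in hepatocytes and in the other tested types together. Those counts are in the closing section. Cib3 (ENSMUSG00000074240, chromosome 8, 72204335 to 72212837), a calcium-binding protein, rose from 0.393 ± 0.340 to 27.7 ± 8.59 CPM. This was a log2 fold change of 5.89 (SE 0.49, edgeR adjusted p = 0.0461). Hamp (ENSMUSG00000050440, chromosome 7, 30942368 to 30944032), which encodes the iron hormone hepcidin, rose from 1.17 ± 0.167 to 21.2 ± 7.65 CPM, 18.4-fold (SE 0.32 on the log2 scale, edgeR adjusted p = 0.0273). Pigr (ENSMUSG00000026417, chromosome 1, 130826684 to 130852249), the receptor that carries IgA into bile, rose from 13.9 ± 3.72 to 77.6 ± 3.48 CPM. This was a log2 fold change of 2.47 (SE 0.20, edgeR adjusted p = 0.0273). Cit (ENSMUSG00000029516, chromosome 5, 115845278 to 116008947), a kinase of cell division, rose by 2.99 on the log2 scale (SE 0.29). Mfge8 (ENSMUSG00000030605, chromosome 7, 79133768 to 79149060), a secreted bridge to dying cells, rose by 1.95 (SE 0.13). Among members of the fixed lists, Elf3 (ENSMUSG00000003051, chromosome 1, 135253575 to 135258568), an epithelial transcription factor, rose by 2.31 (SE 0.21). Atf3 (ENSMUSG00000026628, chromosome 1, 191170296 to 191218039), a stress transcription factor, rose by 2.49 (SE 0.27). Scd1 (ENSMUSG00000037071, chromosome 19, 44394455 to 44407879), the fatty acid desaturase, rose by 1.87 (SE 0.15). Aldh1a1 (ENSMUSG00000053279, chromosome 19, 20492715 to 20643465), a retinaldehyde dehydrogenase, rose by 1.36 (SE 0.15). In the deeper and the shallower pair the log2 ratios were 3.79 and 4.92 for Cib3, 3.03 and 3.59 for Hamp and 2.21 and 2.64 for Pigr.

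The remaining 15 called genes were chosen after their values were seen. Prr15l rose by 3.63 on the log2 scale, Cldn23, a claudin, by 3.85, Mtmr11 by 3.54, Dhrs9 by 3.17, Sstr2, a somatostatin receptor, by 2.94, and S100a11 by 1.89. Slc41a2, 2200002D01Rik, C9, Ppl, Mmp15, Smpd3, Pdgfa and Ly6e rose by 1.38 to 2.31. Slc13a5, the citrate transporter, had 0 UMIs in Jag1+/+ hepatocytes and was at least 55.6-fold higher in Jag1+/-, against a floor of 3 UMIs over the genotype. The 24 genes had a median log2 fold change of 2.31, with Slc13a5 at its bound or at its fitted value. Their median log2 ratios were 1.60 in the deeper and 1.90 in the shallower pair of libraries. Without Jag1+/+ replicate 1, Jag1+/+ replicate 2 or Jag1+/- replicate 2, edgeR called 11, 12 and 12 of the 24 genes. Without Jag1+/- replicate 1 it called 126 genes. Cluster 4 held 9 and 47 of the Jag1+/+ hepatocytes and 369 and 884 of the Jag1+/- hepatocytes. Without it edgeR called 0 genes, and in cluster 1 alone 28, with 13 of the 24. Without cluster 4 there were 747 genes at an unadjusted p under 0.05. The 24 genes had positive values without it with a median of 1.64. DESeq2 called 218 genes in all hepatocytes, and 1227 had an unadjusted p under 0.05 by edgeR.

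Sox4 (ENSMUSG00000076431, chromosome 13, 28948919 to 28953713), the transcription factor named in the series title, measured 4.45 and 7.79 CPM in Jag1+/+ hepatocytes and 12.5 and 22.0 CPM in Jag1+/- hepatocytes. Its log2 fold change of 1.47 (SE 0.37) did not pass the test (edgeR adjusted p = 0.360), with 0.62 in the deeper and 2.08 in the shallower pair. Without cluster 4 the value was 0.16 (SE 0.29). Spp1 (ENSMUSG00000029304, chromosome 5, 104435118 to 104441050), osteopontin, had a log2 fold change of 0.97 (SE 0.42), and of 0.48 (SE 0.83) without cluster 4. Epcam (ENSMUSG00000045394, chromosome 17, 87635979 to 87651129), an epithelial adhesion molecule, had 1.08 (SE 0.63). Sox9 (ENSMUSG00000000567, chromosome 11, 112782224 to 112787760), a biliary transcription factor, had 0.16 (SE 0.19). The receptor gene Notch2 (ENSMUSG00000027878, chromosome 3, 98013527 to 98150361) had 0.20 (SE 0.11), and the Notch target Hes1 (ENSMUSG00000022528, chromosome 16, 30064384 to 30067796) -0.04 (SE 0.28). The keratin genes Krt19 (ENSMUSG00000020911, chromosome 11, 100140810 to 100148665) and Krt7 (ENSMUSG00000023039, chromosome 15, 101411043 to 101430313) were too low to test in hepatocytes, as was the Notch target Hey1 (ENSMUSG00000040289, chromosome 3, 8663359 to 8667256). Hey1 had a log2 fold change of -0.60 (SE 0.47) in sinusoidal endothelium and 0.26 (SE 0.25) in Kupffer cells.

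**Figure D2:**
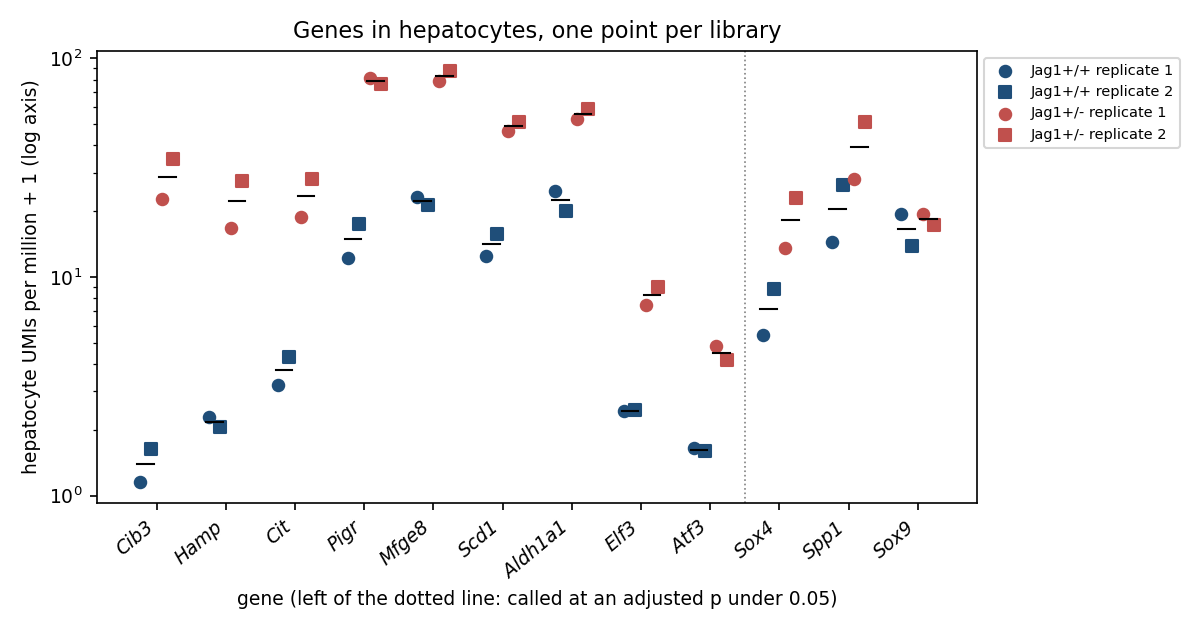
CPM plus 1 in hepatocytes (log axis) for 12 genes in each library, with genotype means as black bars; blue marks Jag1+/+ and red Jag1+/-, circles replicate 1 and squares replicate 2. The 9 called genes left of the dotted line separate the genotypes, with Pigr at 13.9 against 77.6 CPM on average, while Sox4, Spp1 and Sox9 on the right did not pass the test.

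Cholesterol synthesis genes were higher as a list in Jag1+/- hepatocytes, where 20 of 22 measured members had positive values. Their median log2 fold change was 0.72, and 0.38 without Jag1+/- replicate 2 (limma camera adjusted p = 9.10e-09, adjusted p = 0.937 with an estimated correlation). Of these, 10 rose when adjusted over the list alone and 0 over all genes. Sqle, squalene epoxidase, rose by 2.01 (SE 0.40), Idi1 by 1.34 (SE 0.34) and Lss by 1.00 (SE 0.16). Hmgcs1 had -0.02 and did not pass. Lipogenesis genes had a median of 0.25 over 12 members (limma camera adjusted p = 0.0153, adjusted p = 0.937 with an estimated correlation). Scd1, Elovl6 at 1.92 (SE 0.30) and fatty acid synthase Fasn at 0.53 (SE 0.15) rose when adjusted over the list alone and Scd1 over all genes. The call of the lipogenesis list was lost without Jag1+/+ replicate 2 (adjusted p = 0.326 by limma camera) and without Jag1+/- replicate 2 (0.216), with medians of 0.14 and 0.09. Fatty acid oxidation genes were lower in 15 of 16 members, with a median of -0.25 (limma camera adjusted p = 0.000329, adjusted p = 0.937 with an estimated correlation). None of them passed alone: edgeR called 0 when adjusted over the list alone and 0 over all genes, with Cpt1a of carnitine transfer at -0.32 (SE 0.12). Without cluster 4 the fatty acid oxidation median was -0.14.

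Acute phase genes had a median log2 fold change of 0.60, with 12 of 17 members positive (limma camera adjusted p = 0.000284, adjusted p = 0.937 with an estimated correlation). When adjusted over the list alone 5 rose, which were Hamp, Saa1 at 1.11 (SE 0.24), Socs3 at 1.01 (SE 0.20), Hpx at 0.76 (SE 0.17) and Steap4 at 0.60 (SE 0.13), and over all genes only Hamp did. Hpx is a leading gene of cluster 4, whose cells were more numerous in Jag1+/-. The NF-kB and chemokine list had a median of 0.97 with 9 of 11 members positive (limma camera adjusted p = 0.000199, adjusted p = 0.937 with an estimated correlation). Cxcl10 at 1.24 (SE 0.21) was its 1 member that rose when adjusted over the list alone. Antigen presentation genes were positive in 12 of 12, with a median of 0.34 and Cd74 at 0.89 (SE 0.11) past the list alone (limma camera adjusted p = 0.000150, adjusted p = 0.937 with an estimated correlation). Interferon response genes had a median of 0.36 with 14 of 18 positive, 0 of them past the list alone, and Isg15 at 0.40 (SE 0.15) (limma camera adjusted p = 0.00151, adjusted p = 0.937 with an estimated correlation). Immediate early and heat shock genes, which respond to tissue dissociation, had a median of 0.37 with 14 of 16 positive (limma camera adjusted p = 0.00575, adjusted p = 0.937 with an estimated correlation). Of these, Ier3 at 1.82 (SE 0.33) and Jund at 0.52 (SE 0.12) rose when adjusted over the list alone. Over all genes edgeR called 0 members of these last 4 lists, with Cxcl10, Cd74, Isg15, Ier3 and Jund each at an unadjusted p under 0.05. Among hepatocyte lists adjusted on their own by limma camera, the interferon call was lost without Jag1+/+ replicate 1 (adjusted p = 0.0505) and the immediate early call without Jag1+/+ replicate 2 (adjusted p = 0.268). The immediate early median was 0.89, 0.22, 0.82 and 0.21 without Jag1+/+ replicates 1 and 2 and Jag1+/- replicates 1 and 2. Without Jag1+/- replicate 2 the antigen presentation median was 0.16 and the interferon median 0.19, and without cluster 4 the NF-kB and chemokine median was 0.48.

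Pericentral zonation genes, which mark hepatocytes near the central vein, were lower in 15 of 19 members with a median log2 fold change of -0.55 (limma camera adjusted p = 0.00618, adjusted p = 0.937 with an estimated correlation). Cyp2e1 fell by 1.06 (SE 0.24), Cyp1a2 by 0.73 (SE 0.16) and glutamine synthetase Glul by 0.67 (SE 0.12) when adjusted over the list alone, while Aldh1a1 rose over the list alone and over all genes. Without cluster 4 the pericentral median was -0.21 and the call was lost (adjusted p = 0.665 by limma camera). Without Jag1+/+ replicate 2 it was -0.28 and without Jag1+/- replicate 2 -0.16. Notch target genes had a median of -0.19 with 1 of 5 positive and did not pass (limma camera adjusted p = 0.0509). Of these, Heyl at -1.67 (SE 0.31) and Nrarp at -0.96 (SE 0.31) fell when adjusted over the list alone, 2 members in all, and 0 fell over all genes. Among hepatocyte lists adjusted on their own, the Notch target list passed (limma camera adjusted p = 0.0291, adjusted p = 0.937 with an estimated correlation over all types), and without cluster 4 it had a median of -0.44 with 0 of 5 positive (0.00690). It did not pass without Jag1+/+ replicate 1 (0.0505), Jag1+/+ replicate 2 (0.326, median -0.09) or Jag1+/- replicate 2 (0.888, median 0.03). Without Jag1+/- replicate 1 it passed with a median of -0.30 (limma camera adjusted p = 0.0489). Mitochondrially encoded genes were lower in 11 of 13 with a median of -0.30 (limma camera adjusted p = 0.00575, adjusted p = 0.937 with an estimated correlation), a call lost without Jag1+/- replicate 2 (median -0.09, adjusted p = 0.216 by limma camera). Without Jag1+/- replicate 1 the median was -0.57.

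The other 11 pathway lists did not pass limma camera in hepatocytes. The unfolded protein and integrated stress response list, with Atf3, had a median of 0.29 (adjusted p = 0.0722), extracellular matrix genes -0.28 (0.345), bile acid synthesis genes -0.18 (0.567), hepatoblast and imprinted fetal genes 0.02 (0.599) and Notch pathway components -0.07 (0.612). Cell cycle genes had a median of -0.04 (0.714), YAP and TEAD targets 0.05 (0.718), NRF2 targets 0.08 (0.838), periportal genes -0.10 (0.843), hypoxia and glycolysis genes 0.02 (0.985) and bile acid and biliary transport genes -0.03 (0.986). Within these lists, Baat at 1.24 (SE 0.26) and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, at 0.64 (SE 0.16) rose when adjusted over the list alone, as did the bile acid exporter subunit Slc51b at 0.77 (SE 0.15). The median and the camera direction differed in sign for the hepatoblast, cell cycle, periportal and transport lists, and the median and the mean for the extracellular matrix list. Among hepatocyte lists adjusted on their own by limma camera, some of these passed under other settings. Cell cycle genes had a median of 0.24 without Jag1+/+ replicate 2 (adjusted p = 0.0417), 0.22 without Jag1+/- replicate 2 (0.0134) and 0.14 without cluster 4 (0.00556), but -0.27 without Jag1+/- replicate 1 (0.0735). Extracellular matrix genes had -0.43 without Jag1+/- replicate 2 (limma camera adjusted p = 1.86e-05) and hepatoblast genes -0.18 without Jag1+/+ replicate 1 (0.00741). The stress response list passed on its own (limma camera adjusted p = 0.0404), with 0.54 without Jag1+/- replicate 1 (3.14e-05) and -0.04 without Jag1+/- replicate 2 (0.806).

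Markers of other cell types also moved in the hepatocyte counts. Sinusoidal endothelial markers were lower in 15 of 15 members with a median log2 fold change of -0.66 (limma camera adjusted p = 2.28e-10, adjusted p = 0.920 with an estimated correlation). Of them 13 fell when adjusted over the list alone, with Lyve1 at -1.15 (SE 0.22) and Stab2 at -0.57 (SE 0.12). Cholangiocyte markers were positive in 12 of 13 with a median of 0.62 (limma camera adjusted p = 1.51e-06, adjusted p = 0.920 with an estimated correlation). When adjusted over the list alone 6 rose, with Cldn7 at 4.55 (SE 0.52), Bicc1 at 2.56 (SE 0.36) and Clu at 1.70 (SE 0.21) beside Elf3. Over all genes Elf3 alone passed. Central vein markers had a median of -0.84 (limma camera adjusted p = 0.000832, and 0.920 with an estimated correlation) and stellate markers -0.33 (0.0133, and 0.927). Kupffer markers had -0.36 (limma camera adjusted p = 0.0193, and 0.978 with an estimated correlation) and T and NK markers 0.35 (0.0388, and 0.920). The marker lists of hepatocytes, portal endothelium, dendritic cells, monocytes, neutrophils, B cells and erythroid cells did not pass over all cell types, at medians of -0.20, -0.41, 0.35, 0.30, 0.33, -0.26 and 0.58. Adjusted in hepatocytes alone, the hepatocyte markers (limma camera adjusted p = 0.0343) and the portal endothelial markers (0.0356) passed. The hepatocyte markers also passed without Jag1+/+ replicate 2 (0.0365) or Jag1+/- replicate 2 (0.0124), but not without Jag1+/+ replicate 1 (0.166), Jag1+/- replicate 1 (0.497) or cluster 4 (0.473, median -0.05), all by limma camera. With 1 library left out other lists passed on this adjustment. Neutrophil markers had 1.55 without Jag1+/+ replicate 2 (adjusted p = 0.00118 by limma camera) and 0.92 without Jag1+/- replicate 2 (0.000272), but -1.04 without Jag1+/- replicate 1. Monocyte markers had 1.06 (0.0130) and 0.70 (0.000416) without the same replicates 2, and B cell markers -0.81 without Jag1+/+ replicate 1 (1.23e-05) and -0.97 without Jag1+/- replicate 1 (0.0340). Portal endothelial markers had -0.61 without Jag1+/+ replicate 1 (0.000783) and -0.86 without Jag1+/- replicate 2 (0.00125), but did not pass without Jag1+/+ replicate 2 (0.551) or Jag1+/- replicate 1 (0.282). Dendritic cell markers passed without Jag1+/+ replicate 2 (limma camera adjusted p = 0.0207) and with 0.53 without Jag1+/- replicate 2 (0.0108), and neutrophil markers also without cluster 4 (0.0254). B cell markers changed sign to 0.54 without Jag1+/+ replicate 2 (limma camera adjusted p = 0.106). Over the tested cell types limma camera called 30 of 88 tests of marker lists, and 0 with an estimated correlation, at adjusted p from 0.920 to 0.978. The stellate call was lost without Jag1+/- replicate 1 (adjusted p = 0.886), the Kupffer call without Jag1+/+ replicate 2 (0.373) or Jag1+/- replicate 2 (0.781), and the T and NK call without Jag1+/+ replicate 2 (0.400), all by limma camera. Without Jag1+/+ replicate 2 the cholangiocyte marker median was 1.07. The stellate marker median was -1.10 without Jag1+/- replicate 2, the Kupffer marker median -0.61 and -0.94 without Jag1+/+ replicate 1 and Jag1+/- replicate 1, and the T and NK marker median 0.64 without Jag1+/+ replicate 1.

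**Figure D3:**
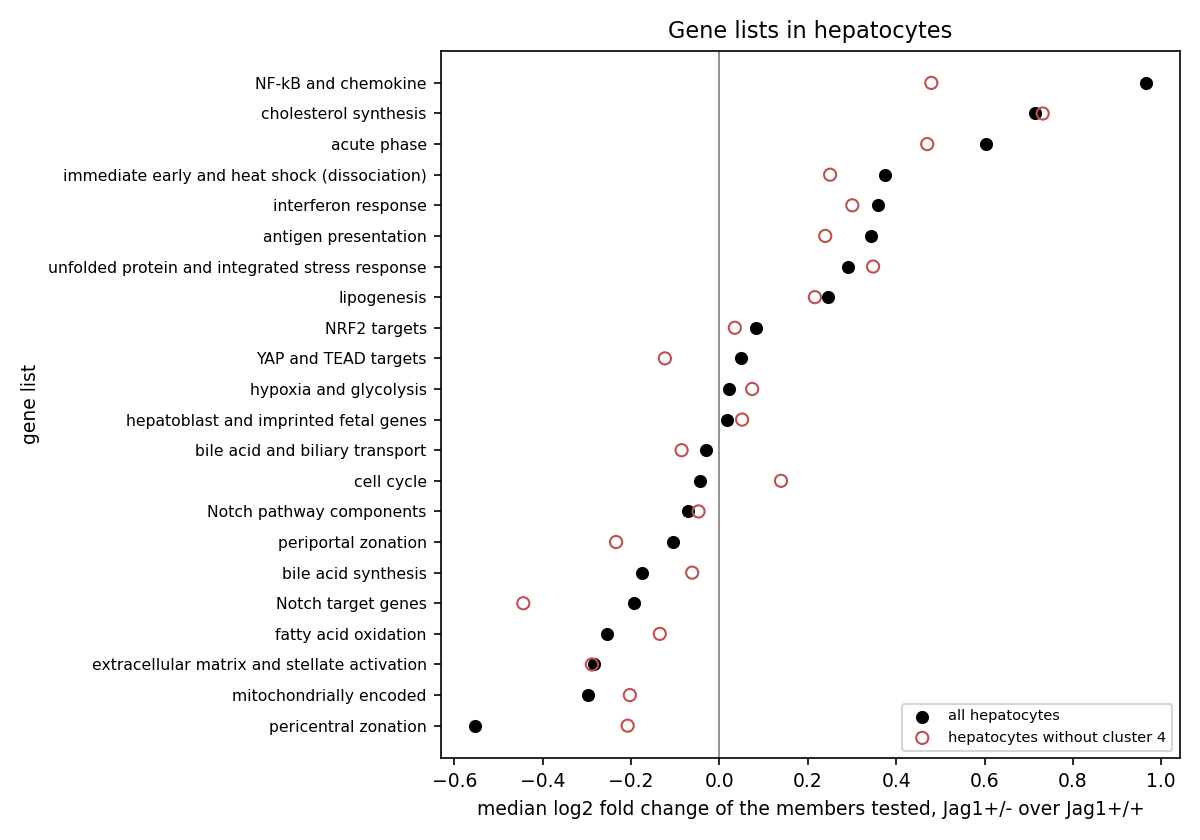
Median log2 fold change (Jag1+/- over Jag1+/+) of the members of 22 pathway lists in hepatocytes; filled black points use all hepatocytes and open red points leave out cluster 4. The cholesterol synthesis median was 0.72 and then 0.73, and the pericentral median -0.55 and then -0.21.

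In the immune cell types, 7 genes rose and 0 fell by edgeR. In neutrophils, where 8521 genes were tested, Clec4n (ENSMUSG00000023349, chromosome 6, 123229843 to 123247021), the receptor dectin-2, rose from 4.41 ± 0.573 to 43.2 ± 20.5 CPM. This was a log2 fold change of 3.30 (SE 0.45, edgeR adjusted p = 0.00490). Bcl2a1b (ENSMUSG00000089929, chromosome 9, 89199209 to 89207827), of a survival gene family whose members share sequence, rose from 2.59 ± 1.78 to 24.8 ± 9.68 CPM, by 3.06 (SE 0.51, edgeR adjusted p = 0.0202). Irg1 (ENSMUSG00000022126, chromosome 14, 103046977 to 103056573), which makes itaconate and was chosen after its values were seen, had 0 UMIs in Jag1+/+ and was at least 16.6-fold higher in Jag1+/-. In T and NK cells, Ifitm1 (ENSMUSG00000025491, chromosome 7, 140967221 to 140969825), an interferon-induced membrane protein, rose from 7.39 ± 1.92 to 66.5 ± 11.5 CPM, by 3.14 (SE 0.28, edgeR adjusted p = 0.0277). In monocytes and macrophages, Ms4a7 (ENSMUSG00000024672, chromosome 19, 11321039 to 11336146), a macrophage membrane protein, rose 61.0-fold from 2 UMIs in Jag1+/+ (counting interval 16.7 to 506, edgeR adjusted p = 0.0108). Gzma (ENSMUSG00000023132, chromosome 13, 113093825 to 113100981), the protease granzyme A, rose 42.0-fold from 2 UMIs in Jag1+/+ (counting interval 11.5 to 349, edgeR adjusted p = 0.0124). Basp1 (ENSMUSG00000045763, chromosome 15, 25363277 to 25413764) rose from 5.69 ± 4.33 to 70.8 ± 3.41 CPM, by 3.37 (SE 0.44, edgeR adjusted p = 0.0463). The log2 ratios of these 7 genes lay between 2.75 (Bcl2a1b) and 4.82 (Gzma) in the deeper pair and between 2.57 (Clec4n) and 6.91 (Ms4a7) in the shallower pair. Ms4a7 is a leading gene of cluster 35, which held 3 and 5 cells in Jag1+/+ and 73 and 25 in Jag1+/-, and cluster 37 held 26 and 60 against 133 and 48. Among neutrophils cluster 38 held 55 and 68 cells in Jag1+/+ and 334 and 89 in Jag1+/-. The neutrophil count of 3 became 0 without Jag1+/+ replicate 2, 187 without Jag1+/- replicate 1 and 60 without Jag1+/- replicate 2, and without Jag1+/+ replicate 1 it was 3 other genes. Clec4n, Bcl2a1b and Irg1 in neutrophils were lost from edgeR's calls without Jag1+/+ replicate 1, Clec4n at an adjusted p of 0.107, and Bcl2a1b also without Jag1+/- replicate 1. The T and NK count of 1 became 0 without either Jag1+/+ replicate, 220 without Jag1+/- replicate 1 and 124 without Jag1+/- replicate 2, and the monocyte and macrophage count of 3 became 7, 27, 7 and 36 without Jag1+/+ replicates 1 and 2 and Jag1+/- replicates 1 and 2. Without doublets Clec4n and Ifitm1 stayed called, 2 of the 7, and Gzma was too low to test in monocytes and macrophages. Gzma is a T and NK marker, at 3015 and 4424 CPM on average in the T and NK cells of the genotypes, so RNA of such cells in monocyte droplets is not excluded. DESeq2 called 2, 1 and 6 genes in these types, and 227, 140 and 257 had an unadjusted p under 0.05 by edgeR.

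In 6 cell types edgeR called 0 genes, and the genes with the smallest p are given as values. Stellate cells had Gsn (ENSMUSG00000026879, chromosome 2, 35256380 to 35307892), an actin-severing protein, at 1.71 (SE 0.34) on the log2 scale. They also had Emp1 (ENSMUSG00000030208, chromosome 6, 135362545 to 135383173) at 1.95 (SE 0.39). This class of stellate cells and fibroblasts drew 6.31% and 9.33% of its cells from cluster 6 in Jag1+/+ and 17.0% and 28.8% in Jag1+/-. Sinusoidal endothelium had Cfap69 (ENSMUSG00000040473, chromosome 5, 5579278 to 5664239) at 1.35 (SE 0.21) and Abcc9 (ENSMUSG00000030249, chromosome 6, 142587862 to 142702315), a potassium channel subunit, at 0.98 (SE 0.18). The Pcna pseudogene Pcna-ps2 (ENSMUSG00000067608, chromosome 19, 9283380 to 9284160) stood there at 35.0-fold over 3 UMIs in Jag1+/+ (counting interval 11.6 to 173). B cells had the calcium-binding genes S100a6 (ENSMUSG00000001025, chromosome 3, 90612882 to 90624181) at 1.68 (SE 0.21) and S100a4 (ENSMUSG00000001020, chromosome 3, 90603771 to 90606045) at 1.76 (SE 0.33). The peptide transporter Slc15a2 (ENSMUSG00000022899, chromosome 16, 36750177 to 36784962) stood there at 141.7-fold over 1 UMI in Jag1+/+ (counting interval 25.03 to 5638). Dendritic cells had the chemokine Ccl17 (ENSMUSG00000031780, chromosome 8, 94810453 to 94812036) at 3.82 (SE 0.61) and the lectin Mgl2 (ENSMUSG00000040950, chromosome 11, 70130329 to 70137550) at 1.79 (SE 0.33). Serinc3 (ENSMUSG00000017707, chromosome 2, 163623272 to 163645131) stood there at -0.76 (SE 0.14). Kupffer cells had the lectin Cd209g (ENSMUSG00000079168, chromosome 8, 4134098 to 4137707) at -0.93 (SE 0.12). They had Lrg1 (ENSMUSG00000037095, chromosome 17, 56119678 to 56122001) at 1.91 (SE 0.24) and Pcna-ps2 at 4.46 (SE 0.62). Erythroid cells had Cd52 (ENSMUSG00000000682, chromosome 4, 134082448 to 134095082) at 3.52 (SE 0.47), and the class II genes H2-Aa (ENSMUSG00000036594, chromosome 17, 34282744 to 34287823) at 3.19 (SE 0.49) and H2-Eb1 (ENSMUSG00000060586, chromosome 17, 34305867 to 34316674) at 20.5-fold over 3 UMIs in Jag1+/+ (counting interval 6.72 to 101.6). Cd74, of antigen presentation, measured 10.8 CPM there in Jag1+/+ and 206 CPM in Jag1+/- on average. RNA of immune cells in erythroid droplets is therefore not excluded. At an unadjusted p under 0.05 edgeR had 151 genes in stellate cells, 173 in sinusoidal endothelium, 38 in B cells, 117 in dendritic cells, 109 in Kupffer cells and 52 in erythroid cells. DESeq2 called 1, 1, 3, 0, 5 and 1 in the same order. Without Jag1+/- replicate 1 edgeR called 78, 19, 1, 30, 36 and 7 genes in the same order, and without Jag1+/- replicate 2 it called 148, 47, 1, 11, 10 and 4. Without Jag1+/+ replicate 1 or 2 it called 9 or 7 in stellate cells and 0 in the others. The simulated data were 1 draw per type, with genes varying independently and only genes of at least 20 mean CPM changed. In them, 2-fold changes were recovered in 95.5% of the changed hepatocyte genes and in 4.48% to 61.2% in the other types. These shares do not cover lower genes or variation shared between genes, so they do not give the recovery in the data. Of the calls in these simulations, 25 of 221 in hepatocytes and 25 of 138 in erythroid cells were false. With no gene changed the test called 0 genes in hepatocytes and neutrophils, 1 in monocytes and macrophages, 6 in T and NK cells, where Ifitm1 was the 1 gene called in the data, and 10 in Kupffer cells. None of 11891, 11925 and 11803 genes passed the edgeR test of a difference in response between hepatocytes and sinusoidal endothelium, Kupffer cells or B cells.

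Gene lists moved in these types too, and limma camera called 54 of 203 tests of pathway lists over the 10 cell types. With an estimated correlation 0 were called, at adjusted p from 0.937 to 0.998, and fry called 0. These settings were not tried on simulated lists, so the absence of calls under them does not show that the lists were unchanged. Neutrophils had 9 of 9 NF-kB and chemokine genes positive with a median log2 fold change of 1.00 (limma camera adjusted p = 3.08e-08). Cxcl10 at 2.54 (SE 0.54), Ccl4 at 3.41 (SE 0.79) and Icam1 at 1.84 (SE 0.62) rose when adjusted over the list alone, but 0 over all genes. Cell cycle genes were positive in 4 of 28 in neutrophils with a median of -0.42 (limma camera adjusted p = 8.66e-06). The neutrophil class drew 28.7% and 27.3% of its cells from cluster 39 in Jag1+/+ and 12.2% and 14.1% in Jag1+/-. Its share from cluster 38 was 36.7% and 23.8% in Jag1+/+ and 53.6% and 54.6% in Jag1+/-. Stellate markers were positive in 6 of 6 in neutrophils with a median of 1.58 (limma camera adjusted p = 1.10e-07). Interferon response genes were positive in 15 of 18 in B cells with a median of 0.37 (limma camera adjusted p = 1.92e-06). They were positive in 14 of 17 in monocytes and macrophages with 0.46 (limma camera adjusted p = 3.40e-06). NF-kB and chemokine genes were positive in 9 of 9 in sinusoidal endothelium with a median of 0.58 (limma camera adjusted p = 0.000150). In stellate cells 5 of 5 were positive with 0.83 (limma camera adjusted p = 2.77e-05). Cholesterol synthesis genes were positive in 18 of 21 in sinusoidal endothelium with a median of 0.26 (limma camera adjusted p = 0.000460) and 19 of 20 in T and NK cells with 0.26 (limma camera adjusted p = 0.000461). Mitochondrially encoded genes had negative medians and passed in 9 types, from -0.94 in stellate cells (limma camera adjusted p = 6.86e-09) and -1.27 in monocytes and macrophages to -0.30 in hepatocytes. The median over the 10 types was 0.0115 in the deeper pair, below 0 in 5 types, and -1.10 in the shallower pair, which holds the mitochondria-rich Jag1+/+ replicate 1. Notch target genes, Notch pathway components, bile acid synthesis, bile acid and biliary transport, periportal zonation and NRF2 targets passed in no cell type.

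Cholangiocytes, the cells that form Notch-dependent bile ducts, fell below the minimum with 10 cells in Jag1+/+ replicate 1, and their values are given without a test. Spp1 measured 27476 and 26807 CPM in Jag1+/+ cholangiocytes and 15207 and 9130 in Jag1+/- cholangiocytes. The hepatocyte gene Ahsg measured 1357 and 2392 CPM against 7079 and 16399 in the same cells, on TMM-scaled totals. RNA of hepatocytes in cholangiocyte droplets is therefore not excluded, and it would lower the CPM of the cholangiocytes' own genes. Sox9 measured 798 and 636 CPM against 422 and 232, and Epcam 1064 and 1072 CPM against 653 and 387. Krt19 measured 150.4 and 519.8 CPM against 120.7 and 59.2, and Krt7 57.8 and 58.7 CPM against 48.0 and 15.7. Sox4 measured 1319 and 799 CPM against 782 and 713, Hes1 382 and 233 against 195 and 151, and Notch2 69.4 and 40.9 against 34.7 and 31.5. Jag1 had 0 UMIs in the cholangiocytes of Jag1+/+ replicate 1, with an exact Poisson interval of up to 42.7 CPM, and measured 27.3, 46.3 and 35.2 CPM in the other libraries. Portal and arterial endothelium, also untested, had Jag1 at 335 and 228 CPM in Jag1+/+ and 141.5 and 123.6 in Jag1+/-. The exact Poisson intervals of Jag1 in portal and arterial endothelium were 209.8 to 507 and 183.5 to 281 CPM in Jag1+/+ and 105.6 to 185.5 and 69.2 to 204 in Jag1+/-. They came from 16 and 55 cells in Jag1+/+ and 38 and 20 in Jag1+/-. Such intervals cover counting error only, and not the variation between cells or animals.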

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

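The comparison of the 24 hepatocyte genes in cluster 8 was chosen after the result was seen. Cluster 8, which stayed unnamed and was not among the hepatocytes tested in the report, held 9265063 and 3242249 UMIs in Jag1+/+ and 2889836 and 8498626 in Jag1+/-, and the 24 genes had a median log2 ratio of 1.47 there between Jag1+/- and Jag1+/+. In 22 of the 24 the values of both Jag1+/- libraries lay above those of both Jag1+/+ libraries. The 24 genes were called in hepatocytes of the same animals, so cluster 8 gives no independent support. Among all genes tested in hepatocytes 38.7% were separated by genotype in 1 direction or the other, and that share was not computed in cluster 8. Some of the 24 had few counts there, as Slc13a5 with 0 and 0 UMIs in Jag1+/+ and 1 and 5 in Jag1+/-.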

How the results depend on the processing

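The depth pairs as a block, the hepatocyte subsets, the doublet threshold, the hepatocyte lists with libraries left out and the cholangiocyte test below the minimum were chosen after the data were seen, the other settings before. The hepatocyte count of 24 became 218 with the DESeq2 Wald test, 162 without a filter on low counts, 19 with the replicate numbers as a block, which kept 13 of the 24, 40 in stricter cells, 41 without doublets, 42 with cluster 8, 0 without cluster 4, 28 in cluster 1 alone with 13 of the 24, 0 in cluster 2 alone and 3 in cluster 3 alone. Leaving out 1 library gave 17 to 126, in fits where its genotype keeps 1 animal that is assumed to vary like the animals of the other genotype. The 7 genes changed in the other cell types, summed, became 20 with the Wald test, 186 without a filter, 1 with the replicate numbers as a block, 2 without doublets and 19 to 585 with 1 library left out. The 149 calls of the cholangiocyte test became 352 with the replicate block, 59 with the Wald test, 355 without a filter, 48 thinned and 104 to 512 with 1 library left out. Shares gave 2 calls in unmerged clusters, clusters 4 and 35, and 0 under every other setting run. The 54 list calls became 0 with an estimated correlation and 0 with fry, and Jag1 had 0 calls under every setting run. The stress response list in hepatocytes turned from Up to Down without Jag1+/- replicate 2 (limma camera adjusted p = 0.806), and its adjusted p ranged from 3.14e-05 to 0.806 with 1 library left out. Of 480 recomputed values of the 31 called genes over these settings, 333 kept the call and 147 lost it. Over all single genes followed, called or not, 1076 values kept their status, 147 lost a call, 45 gained one and 0 reversed. Of the values of the cholangiocyte genes 401 kept it, 61 lost it and 19 gained it. Lists in hepatocytes gave 94, 10 and 5 in the same order, and 1 reversed. Residual correlations of same-number libraries were negative, from -0.0640 in B cells to -0.467 in Kupffer cells. These counts thus gave no sign that the replicate numbers pair the libraries. With 2 libraries per genotype, the crossed numbers must give the same values with the opposite sign, which adds nothing. The crossed numbers are the depth pairs, of which the deeper shares a B in its library names. With these pairs as a block the counts were 383 in hepatocytes, 124 in the other types, 116 in cholangiocytes, 61 lists and 0 shares. Splitting the libraries by depth in place of genotype called 0 genes in hepatocytes, 388 in erythroid cells, 386 in Kupffer cells and 179 in B cells. The cause of these shifts was not tested.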

Other observations

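The cholangiocyte test, made below the minimum number of cells, and all genes named from it were chosen after the data were seen. In that test edgeR called 149 of 8424 genes, of which 107 rose and 42 fell in Jag1+/- cholangiocytes. Spp1, a cholangiocyte marker, fell from 27281 ± 375 to 12749 ± 3896 CPM (SD, 2 animals each). This was a log2 fold change of -1.10 (SE 0.26, edgeR adjusted p = 0.0434), with -0.80 in the deeper and -1.46 in the shallower pair. The mucin gene Muc1 (ENSMUSG00000042784, chromosome 3, 89229057 to 89233381) fell from 76.8 ± 43.0 to 0.410 ± 0.580 CPM, 194-fold lower with 1 UMI in Jag1+/- (counting interval 33.9 to 7757). Ttyh1 (ENSMUSG00000030428, chromosome 7, 4119408 to 4136708) had 0 UMIs in Jag1+/- and was at least 28.4-fold lower, Mmd2 (ENSMUSG00000039533, chromosome 5, 142562358 to 142608800) fell by 4.70 on the log2 scale (SE 0.48), and the chloride channel Ano1 (ENSMUSG00000031075, chromosome 7, 144588549 to 144751974) fell by 4.01 (SE 0.88). The growth factor Ptn (ENSMUSG00000029838, chromosome 6, 36714929 to 36810220) was 32.3-fold lower with 3 UMIs in Jag1+/- (counting interval 10.3 to 163). The BMP targets Id1 and Id3 fell by 2.29 (SE 0.30) and 2.17 (SE 0.29), cyclin D1 (Ccnd1) by 1.97 (SE 0.26) and the progenitor marker Prom1 by 1.29 (SE 0.29). Sox9 at -1.06 (SE 0.28), Epcam at -0.99 (SE 0.26) and Krt19 at -2.08 (SE 0.52) did not pass (edgeR adjusted p = 0.0763, 0.0685 and 0.135).

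The genes given here that rose in Jag1+/- cholangiocytes are single genes among the 107, and no list was tested in this type. The protease inhibitor Slpi (ENSMUSG00000017002, chromosome 2, 164354070 to 164389095) was 184-fold higher over 1 UMI in Jag1+/+ (counting interval 32.9 to 7294), and the chemokine Cxcl13 (ENSMUSG00000023078, chromosome 5, 95956951 to 95961068), without a UMI in Jag1+/+, was at least 7.47-fold higher. Syt12 (ENSMUSG00000049303, chromosome 19, 4445908 to 4477447) was at least 6.76-fold higher, Lhfp (ENSMUSG00000048332, chromosome 3, 53041528 to 53261679) 68.9-fold higher over 1 UMI (12.2 to 2737), and the phosphatase gene Dusp10 (ENSMUSG00000039384, chromosome 1, 184013302 to 184075636) 29.6-fold higher over 1 UMI (5.14 to 1185). Lipocalin Lcn2 rose by 2.47 on the log2 scale (SE 0.35), the chemokine Ccl2 by 2.16 (SE 0.41), complement C3 by 2.37 (SE 0.30) and fibronectin Fn1 by 1.58 (SE 0.24). The YAP target Cyr61 rose from 80.5 ± 1.02 to 299.6 ± 22.2 CPM (SE 0.29 on the log2 scale, edgeR adjusted p = 0.00192). Pigr rose by 2.33 (SE 0.43) in cholangiocytes as it did in hepatocytes, and the basolateral bile acid pump Abcc3 by 1.98 (SE 0.37). Hepatocyte genes were higher beside them, with Hpx at 3.58 (SE 0.52), Ahsg at 2.62 (SE 0.43) and Fgb at 2.40 (SE 0.31). RNA of hepatocytes in cholangiocyte droplets is therefore not excluded for the rises of genes that hepatocytes also express. Such RNA would also lower the CPM of cholangiocyte markers, among them those that fell above. Without Jag1+/+ replicate 1, Jag1+/- replicate 1 and Jag1+/- replicate 2 the count of 149 became 452, 512 and 104, and without Jag1+/+ replicate 2 it was 131.

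Of the tests on the 24 hepatocyte genes, the first on cholangiocyte RNA was set before its result was seen and the others were chosen after. The first counted genes lower in cholangiocytes than in hepatocytes in both Jag1+/- libraries and found 3 of 24, short of the 12 that would have excluded cholangiocyte RNA, and 16 of 24 were higher there in both, as cholangiocyte RNA would predict; the rises would however need a median of 17.1% cholangiocyte RNA where the level of Spp1 allows at most 0.578%, in 24 of 24 genes. For the shallow, mitochondria-rich Jag1+/+ replicate 1 alone, the median log2 ratio was 1.60 in the deeper pair, which leaves it out. The genes were called with that pair among the libraries, so this ratio cannot decide the question. Without cluster 4, 24 of 24 genes stayed more than 2 SE above 0. The genes were called with the cells of the other hepatocyte clusters included, so these values cannot decide whether cluster 4 is the whole cause. At least a part may come from cluster 4: the median went from 2.31 to 1.64 and the calls ended, with a smallest adjusted p by edgeR of 0.0758. The calls also ended for genes whose fold moved by less than its SE (Slc41a2, 2.28 with SE 0.16 before and 2.16 with SE 0.16 after). A difference between the genotypes remains open as a hypothesis beside cluster 4, and so does any difference between animals that the labels do not give.

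On the genes with 1 sign of change in all 10 tested cell types and an unadjusted p under 0.05 in at least 3 of them, 6 of the 157 with 1 sign, the tests of a strain segment and of the pseudogene were chosen after the result was seen, and the test of free hepatocyte RNA before. Of these 6 genes 3, or 50%, lie on chromosome 2 with Jag1 (Serinc3, Tgm2 and Pcna), against 7.79% of 4698 background genes, but the idea of a segment of another strain linked to the Jag1 allele came from these genes. Other genes were taken with tests in at least 5 types, 1 sign in each and the same limit on p. Of them 9.09% lie there, 1 of 11 (Cdk5rap1, Fisher exact p = 0.590), with an exact 95% upper bound of 41.3%. Pcna-ps2, taken up below, is counted among those elsewhere. With the first set included 4 of 17 lie there (Fisher exact p = 0.0387), but that set gave the idea. So few genes cannot decide, and the segment stays open, with no sequence examined. Free hepatocyte RNA, at 16.7% of the 6 genes under the limit set for it, stays open since 1 gene of 6 (Clu) is too few to decide. Pcna-ps2, with 71 UMIs in Jag1+/+ and 1268 in Jag1+/-, gained a median of 41.2% of what Pcna lost, so reads of a variant Pcna may have been assigned to the pseudogene, which that share leaves undecided.

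For the lower mitochondrially encoded counts of Jag1+/- cells, the tests were chosen after the result was seen. In hepatocytes, damaged cells of Jag1+/+ replicate 1 are argued against, since the list's median log2 fold change was -0.32 without that library (limma camera adjusted p = 0.0146) and its hepatocytes held 22.6% mitochondrially encoded UMIs against 23.0% in both deeper libraries and 16.4% in Jag1+/- replicate 2. Over the 10 cell types such cells may account for a part: the median log2 ratio was 0.0115 in the deeper pair, which leaves that library out, and -1.10 in the shallower pair. Single types differed from this, with stellate cells at -0.71 and neutrophils at 0.47 in the deeper pair. In hepatocytes the lower share was seen in Jag1+/- replicate 2 alone, and the median was -0.09 in the deeper pair, which leaves that library out. A difference between the genotypes is not shown by these values and was not excluded.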
